A study of Sphingomonas glacialis with 28 samples.

How the data were processed

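RNA of Sphingomonas glacialis strain AAP5 was sequenced from 3 independent cultures, A, B and C, grown in an organic medium under alternating light and dark phases. Per the labels, sampling took place at 1 h and at 6 h of each light phase and each dark phase, counted from the switch that began the phase. On days 5 and 6 each culture gave its own library at each point, which makes 24 libraries in 8 groups of 3. On day 4 each of the 4 points is a single library pooled from cultures A to C. Per the labels' protocols, total RNA was used, ribosomal RNA was removed with the RiboZero kit, and libraries followed a published protocol.

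The deposited values are raw read counts per locus tag, 4071 rows by 28 libraries, as whole numbers that are not normalized. The submitters' processing notes name Bowtie2, SAMtools, featureCounts and edgeR, without versions. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so reads shared by near-identical copies or by overlapping genes may have been split or dropped by the counting. The table does not pair its locus tags with gene names or products, and no annotation was used here. For this reason the 31 gene lists fixed before the data were examined could not be matched to any gene and none was tested, and structural RNA genes were not told apart from protein-coding ones. The rule for named genes, also fixed before the data were examined, then allows at most 2 locus tags that rose and 2 that fell per comparison. These are the largest positive and negative log2 fold changes among genes with an adjusted p below 0.05, with a mean abundance above the median of the tested genes and the same direction in all 3 cultures. A locus tag outside this rule was chosen after its values were seen.

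The count totals of the 24 unpooled libraries ranged from 1570862 to 14374018 with a median of 7865775, and those of the 4 pools from 1670201 to 2696986. The median count per gene was 109 in the shallowest of the unpooled libraries and 693 in the deepest. The 4 most abundant locus tags took 41.6 to 63.6% of the counts of an unpooled library and 25.8 to 59.8% of those of a pool, which lowers the depth left for all others. Chi-square statistics between libraries of a group, divided by their degrees of freedom, lay between 8.53 and 155 over 24 pairs. No pair within a group thus differed as little as sampling noise alone would allow, and no library was a copy of another of its group. Libraries of different groups and the pools were not compared in this way.

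Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10, which left 4063 genes and removed 8. Library sizes were scaled by the trimmed mean of M values (TMM factors 0.832 to 1.33). One mean per day, phase and hour was fitted to the 24 unpooled libraries with the quasi-likelihood F test (robust estimation, two-sided). The common biological coefficient of variation was 14.3%. All adjusted p values in the text are Benjamini-Hochberg values over the 4063 genes of a comparison from this test, a gene was called when its adjusted p was below 0.05, and standard errors are those of the log2 fold change in the same fit. Values of single genes are given as CPM (counts scaled to a common library size) with TMM scaling, mean ± SD over 3 cultures. The 10 comparisons were dark against light over both hours, at 1 h and at 6 h, the interactions of phase with hour and with day, the switch to dark, the switch to light, 6 h against 1 h within light and within dark, and day 6 against day 5. Each averages over days 5 and 6 unless it compares them. The pools of day 4 have no replicates and entered no test. For them the sign and size of the log2 CPM ratio are described.

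In every culture the dark samples were taken 12 h after the light samples of the same day, so a gradual change over the days of culture adds to any difference between dark and light. A contrast chosen after the data were seen removes it. It weights light and dark of day 5 and light and dark of day 6 by -1, 3, -3 and 1, divided by 4, so that a change that is linear or quadratic in time cancels, and is called drift-cancelling. On simulated counts without drift, with 200 of 4059 genes changed, the fixed contrast over both hours recovered 92.5% of the genes changed by 0.5 on the log2 scale and 2.50% of its calls were false. With simulated drift in 4060 genes, the fixed contrast over both hours made 2115 calls, 90.9% of them false, while the drift-cancelling contrast made 208 calls with 4.81% false. The simulated drift was linear and quadratic in time, which the weights cancel by construction, and the simulated libraries were independent. A drift of another form and libraries correlated within cultures were not simulated. At 6 h with drift, the drift-cancelling contrast recovered 73.1% of the genes changed by 0.5 and 4.71% of its calls were false. At 1 h with drift it recovered 67.2% and 6.32% of its calls were false, above the 5% aimed at.

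Also after the data were seen, runs of neighbouring rows of the table were searched for. A run held at least 5 genes called in the same direction, with at most 3 other rows between successive calls. The rows follow the order of the locus tags, which is taken here as the order along the genome without a check against a sequence. The number of neighbouring pairs called in the same direction was compared with 10000 permutations of the calls over the rows, one-sided. The day 5 dark 6 h to day 6 light 1 h step, the 7 successive steps in time, and a covariate for a split of the libraries by the ratio of a pair of abundant genes were further additions after the data were seen.

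Libraries of the same letter come from the same culture, so the letters pair the libraries. The residuals of libraries from the same culture correlated with a mean r of 0.187 across genes over 84 pairs (range -0.23 to 0.69, above 0.1 in 53), against -0.09 between cultures, and 20 of the 24 libraries correlated best with their own culture. The culture as a block was run beside each comparison and is printed where it moved a count by more than 1.5 times. Other alternatives were days 5 and 6 summed per culture, each day alone, RLE scaling, no filter, a mean count of at least 50, DESeq2 1.42.0, removal of the 10 most abundant genes, a fold of at least 2 added to the adjusted p, and leaving out each culture and each library. P values measure the spread between the libraries of a group, with no term for the culture. Each culture gave 8 of the 24 libraries, so libraries of different points are not independent.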

Results

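The data follow the transcriptome of Sphingomonas glacialis AAP5, a cold-tolerant bacterium that, per the title of the study, harvests light with both bacteriochlorophyll-based reaction centres and proton-pumping xanthorhodopsins. Alternating light and dark phases were applied to 3 cultures, and the question taken from the design is which genes change their transcript level with the phase and with the time since the last switch. Read counts were available for 4071 locus tags in 24 libraries of days 5 and 6 (3 cultures at each of 8 points) and in 4 pooled libraries of day 4. Total counts ranged from 1570862 to 14374018 in the unpooled libraries and from 1670201 to 2696986 in the pools. Genes are given by their locus tags because the table pairs them with no names.

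On the first principal component the libraries of day 5 followed the order of sampling, and those of day 6 lay beyond them. The first principal component carried 49.2% of the variance and the second 11.9%. On the first component the group means moved from -27.41 ± 3.68 (SD, n = 3) at 1 h of light on day 5 through -20.5 ± 2.62 and -8.47 ± 1.05 to 1.29 ± 1.73 at 6 h of dark on day 5. On day 6 they moved less and did not follow the order of sampling throughout, with 11.90 ± 0.74 and 10.90 ± 1.10 at 1 h and 6 h of light and 13.25 ± 1.48 and 19.04 ± 2.44 at 1 h and 6 h of dark.

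**Figure D1:**
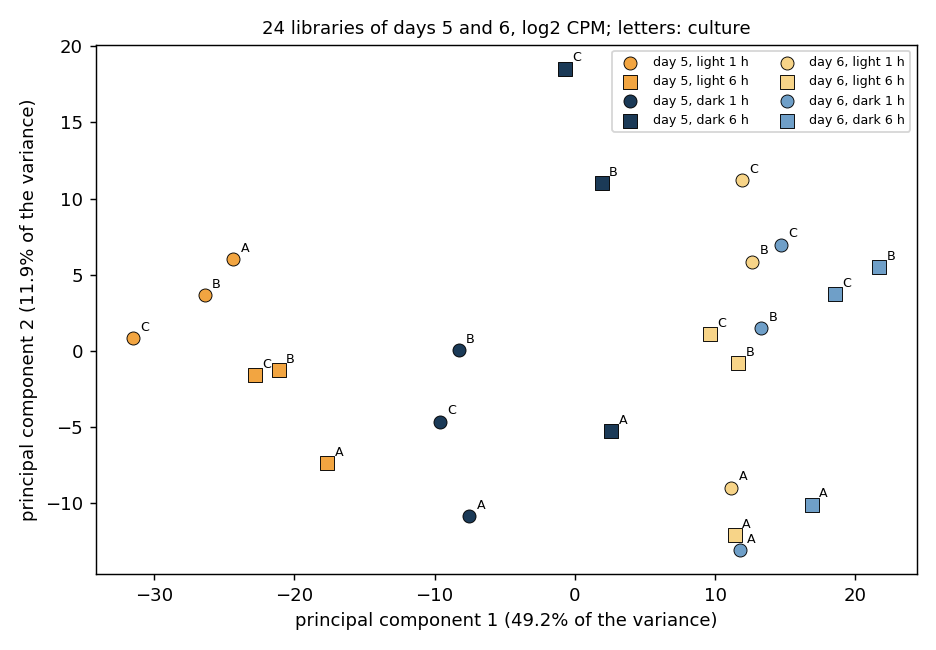
Each point is 1 of the 24 unpooled libraries on principal components 1 (49.2% of the variance) and 2 (11.9%) of log2 CPM, with colour for day and phase, shape for the hours after the switch and the letter for the culture. Day 5 libraries spread from left to right in the order of sampling, and day 6 libraries lie at the right.

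At 6 h after the switch, the largest differences between dark and light lay in 2 stretches of neighbouring genes. In a stretch of 40 genes that contains E2E30_RS16265, 36 genes were higher in the dark and none was lower, with a median of 4.20-fold over the 40 (log2 2.07). In a stretch of 5 genes that contains E2E30_RS05030, all 5 were lower in the dark, with a median log2 difference of -1.80. They are called the dark-raised and the light-raised stretch here, and were found after the values were seen. Both names give the direction at 6 h only. E2E30_RS16265 rose 14.1-fold in the dark (log2 3.81 ± 0.30 SE, adjusted p = 5.63e-08, 6 against 6 libraries), from 38.28 ± 5.97 CPM (SD, n = 3) at 6 h of light to 916 ± 247 CPM at 6 h of dark on day 5, and from 125 ± 40.1 to 1039 ± 477 CPM on day 6. E2E30_RS16275 of the same stretch rose by log2 3.85 ± 0.35 (adjusted p = 4.20e-07). E2E30_RS05030 fell by 3.46 ± 0.23 on the log2 scale (adjusted p = 1.07e-09), from 839 ± 381 to 49.95 ± 12.5 CPM on day 5 and from 1014 ± 60.7 to 139 ± 69.4 CPM on day 6. E2E30_RS05015 fell by 3.20 ± 0.28 on the same scale (adjusted p = 1.68e-07). All 4 genes moved the same way in all 3 cultures, which the rule for named genes requires.

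In all, 475 of 4063 genes were called at 6 h, 226 higher and 249 lower in the dark, 41 of them by at least 2-fold. The count was 775 with the culture as a block, 57 with the days summed per culture and 11 on day 6 alone. With the drift-cancelling contrast 36 genes were called, 30 higher and 6 lower, of which 29 were in the dark-raised and 5 in the light-raised stretch. On that contrast E2E30_RS16265 differed by 3.34 ± 0.33 (adjusted p = 2.34e-06) and E2E30_RS05030 by -3.90 ± 0.27 (adjusted p = 2.68e-09). The median of the dark-raised stretch was 1.62 and that of the light-raised stretch -2.15. Calls made with the fixed contrast fell to 295, 303 and 308 genes without culture B of dark 6 h on day 6, culture B of light 6 h on day 5 and culture C of light 6 h on day 5, to 46 without all libraries of culture B and to 196 without those of culture C.

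**Figure D2:**
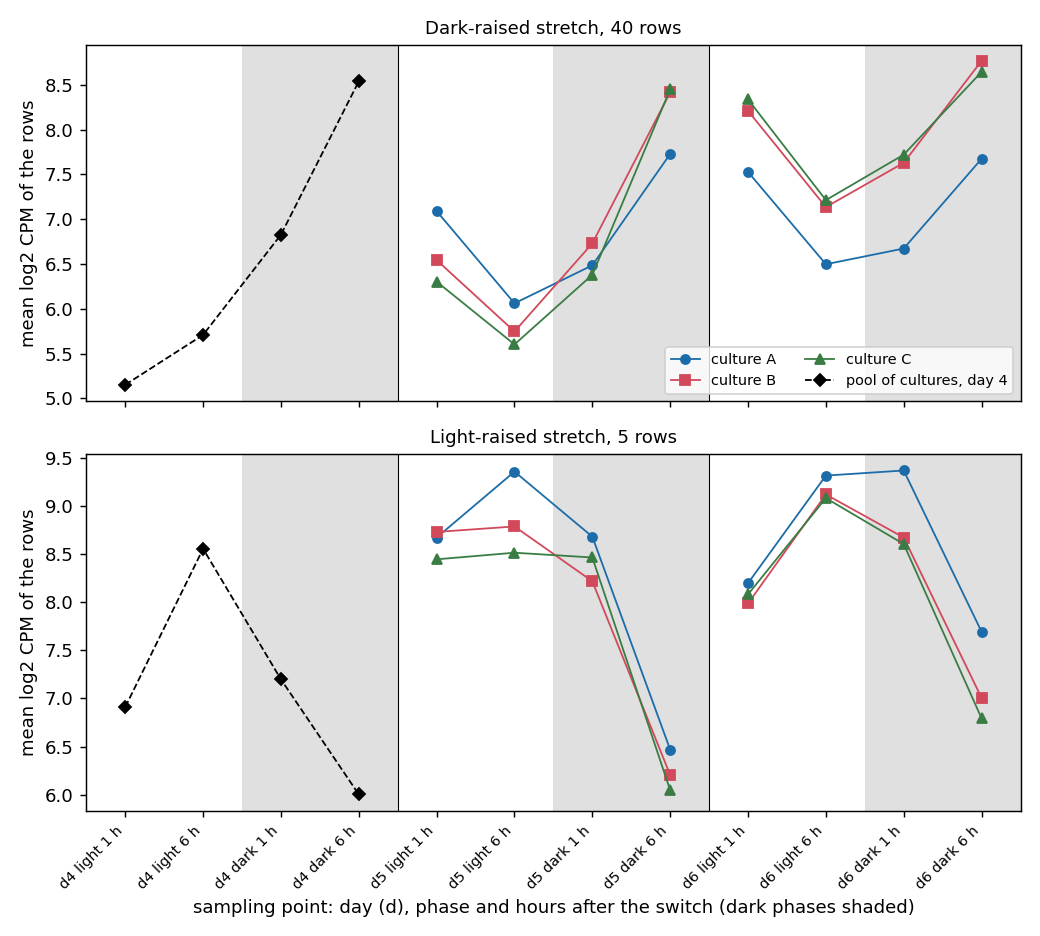
Mean log2 CPM over the 40 genes of the dark-raised stretch and the 5 genes of the light-raised stretch at each sampling point, spaced evenly, for cultures A, B and C on days 5 and 6 and for the single pools of day 4 (dashed), with dark phases shaded. The dark-raised stretch lay at 5.80 ± 0.23 (SD, n = 3) at 6 h of light and 8.20 ± 0.41 at 6 h of dark on day 5, and the light-raised stretch at 8.88 ± 0.43 and 6.24 ± 0.21.

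At 1 h after the switch, genes of the dark-raised stretch went in both directions. There were 13 higher and 16 lower in the dark, and 11 did not pass the threshold. With the drift-cancelling contrast 1 gene was higher, 16 were lower and 23 did not pass, so 12 fewer were called higher, and the median log2 difference was -0.48 in place of 0.02. E2E30_RS16265 was 4.03-fold higher in the dark (log2 2.01 ± 0.28, adjusted p = 6.46e-05) and E2E30_RS16260 3.25-fold (1.70 ± 0.25, adjusted p = 7.26e-05). E2E30_RS16290 and E2E30_RS16280 were lower in the dark, with log2 fold changes of -3.11 ± 0.37 and -2.99 ± 0.35 (adjusted p = 2.56e-05 and 1.76e-05). In the light-raised stretch 2 genes were higher and 3 did not pass the threshold (1 and 4 with the drift-cancelling contrast). On day 6 alone E2E30_RS16265 and E2E30_RS16260 did not pass (log2 fold changes of 1.69 and 1.37, adjusted p = 0.142 and 0.203).

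Across all genes 480 were called at 1 h, 195 higher and 285 lower in the dark, with a median size of 0.43 on the log2 scale. With the culture as a block 721 genes were called, with the days summed per culture 140, on day 6 alone 15, and without culture B or C 75 or 282. The drift-cancelling contrast called 124 genes, 34 higher and 90 lower (267 with the block), and 46 of the 480 were among them with the same direction. This contrast does not cancel a drift that is neither linear nor quadratic in time. Under it E2E30_RS16260 no longer passed the threshold (0.86 ± 0.27, adjusted p = 0.0928), while E2E30_RS16265 (1.22 ± 0.30, adjusted p = 0.0287) and E2E30_RS16290 (-3.72 ± 0.44, adjusted p = 6.77e-05) did.

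Over both hours together, E2E30_RS16265 was 7.52-fold higher in the dark (log2 2.91 ± 0.20, adjusted p = 1.08e-08) and E2E30_RS16260 4.95-fold (2.31 ± 0.18, adjusted p = 1.27e-08). E2E30_RS05030 fell 3.41-fold (log2 -1.77 ± 0.15, adjusted p = 3.09e-08) and E2E30_RS05015 3.04-fold (-1.604 ± 0.185, adjusted p = 3.15e-06). The dark-raised stretch had 22 genes higher and none lower, and the light-raised stretch 4 lower. On day 6 alone E2E30_RS05015 did not pass (log2 fold change of -1.11, adjusted p = 0.141). Across all genes 966 were called, 456 higher and 510 lower, 20 of them by at least 2-fold. With the days summed per culture 246 were called, on day 6 alone 15 and without culture B 234. The genes called at 1 h and at 6 h, from separate libraries of the same cultures, shared 87 higher and 97 lower ones, where independent lists of these sizes would share 10.8 and 17.5. The lists share any drift over the days. With the fixed contrast 15 genes that were lower at 1 h were higher at 6 h, and 2 went the reverse way. With the drift-cancelling contrast the lists shared 1 higher and no lower gene, where independent lists would share 0.251 and 0.133. There too 15 genes that were lower at 1 h were higher at 6 h, and 1 went the reverse way.

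These calls ran parallel to the change between days. Of the 966 genes, 97.7% had the same sign in dark against light as in day 6 against day 5, compared with 79.2% of all tested genes. The drift-cancelling contrast called 58 genes, 18 higher and 40 lower (145 with the culture as a block). Of the 966, 24 were among them with the same direction and 330 had the opposite sign. In the dark-raised stretch 11 genes were still called higher and in the light-raised stretch 4 lower. On the log2 scale E2E30_RS16265 then differed by 2.28 ± 0.22 and E2E30_RS16260 by 1.56 ± 0.20, less than with the fixed contrast. E2E30_RS05030 differed by -1.97 ± 0.17 and E2E30_RS05015 by -1.84 ± 0.21, and all 4 genes were still called.

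**Figure D3:**
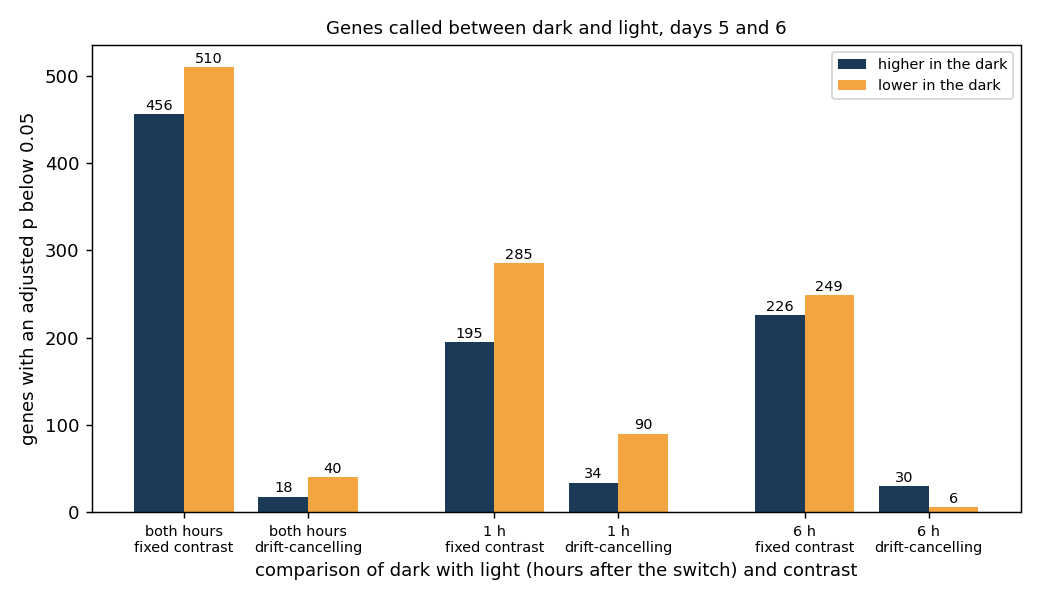
Bars give the number of genes with an adjusted p below 0.05 that were higher or lower in the dark, over both hours, at 1 h and at 6 h after the switch, with the fixed contrast and with the contrast in which linear and quadratic change over time cancels. The counts fall from 966 to 58, from 480 to 124 and from 475 to 36 genes.

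The difference between dark and light changed with the hour for 46 genes, 34 with a larger and 12 with a smaller dark minus light difference at 6 h than at 1 h. Of these, 23 of the 34 lay in the dark-raised stretch and 5 of the 12 made up the whole light-raised stretch. The stretches were chosen by the difference at 6 h, which enters this comparison, so this concentration is partly built in. The values at 6 h also enter the comparisons within light and within dark below. E2E30_RS16290 changed the most, by 6.47 ± 0.53 on the log2 scale (adjusted p = 1.54e-07), followed by E2E30_RS16295 with 6.17 ± 0.49 (adjusted p = 1.40e-07). E2E30_RS05030 and E2E30_RS05015 changed by -3.39 ± 0.30 and -3.18 ± 0.37 (adjusted p = 1.40e-07 and 7.63e-06). With the culture as a block 90 genes were called, and without culture B or C 23 or 25. A linear drift cancels in this comparison by its construction.

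Within the light phase, the transcripts that moved mostly fell. The 6 h samples were always the later ones, so a gradual change over the days adds to this comparison. From 1 h to 6 h of light 34 genes were called, 32 lower and 2 higher, and 17 of the 32 belonged to the dark-raised stretch. E2E30_RS16290 fell by 3.13 ± 0.37 (adjusted p = 9.37e-05), from 380 ± 187 to 43.71 ± 22.0 CPM on day 5 and from 881 ± 371 to 100.1 ± 36.8 CPM on day 6, and E2E30_RS16295 fell by 2.97 ± 0.35 (adjusted p = 9.37e-05). The 2 genes that rose were E2E30_RS05010, in the light-raised stretch, by 1.30 ± 0.27 (adjusted p = 0.0204), and E2E30_RS17305 by 0.36 ± 0.08 (adjusted p = 0.0265). The block called 76 genes. Without culture B, and on day 6 alone, edgeR called 0 (149 and 174 at an unadjusted p below 0.05), so all 4 of these calls were lost, and without culture C it called 8. With the days summed per culture 21 were called. In the fit of both days, the step from 1 h to 6 h of light on day 6 called 12 genes, of which 11 were lower and in the dark-raised stretch. The count was 21 without culture C of light 1 h or culture A of light 6 h on day 5, or without culture A of light 6 h on day 6, and 22 without culture B of light 1 h on day 6.

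Within the dark phase 25 genes of the dark-raised stretch rose, 15 did not pass the threshold, and all 5 genes of the light-raised stretch fell. Here too the 6 h samples were the later ones, so a gradual change adds to the difference. From 1 h to 6 h of dark 76 genes were called, 53 higher and 23 lower. E2E30_RS16290 rose by 3.34 ± 0.38 (adjusted p = 1.79e-05) and E2E30_RS16295 by 3.20 ± 0.35 (adjusted p = 1.42e-05), while E2E30_RS05030 fell 6.83-fold (log2 -2.77 ± 0.22, adjusted p = 2.74e-08) and E2E30_RS05015 5.78-fold (-2.53 ± 0.27, adjusted p = 1.15e-05). With the culture as a block 160 genes were called, with the days summed per culture 47, without culture B or C 11 or 35, and on day 6 alone 2. On day 6 alone E2E30_RS16290, E2E30_RS16295 and E2E30_RS05015 did not pass (log2 fold changes of 2.84, 2.70 and -2.06, adjusted p = 0.108, 0.124 and 0.124).

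By their calls at 1 h and 6 h the 40 genes of the dark-raised stretch fell into classes. A class of 13 genes was higher in the dark at both hours, with median log2 differences of 0.89 and 1.81, and 9 of the 13 were called higher in the switch to dark. This class rests on the fixed contrast, since the drift-cancelling one called 1 gene of the stretch higher at 1 h. A class of 14 genes was lower at 1 h (median -1.99) and higher at 6 h (2.24). All 14 fell within the light phase, with a median log2 change of -2.33, and rose within the dark phase by a median of 2.29, which partly restates the choice of genes that were high at 1 h of light and 6 h of dark. A further 9 were higher at 6 h and did not pass the threshold at 1 h, 2 were lower at 1 h without passing at 6 h, and 2 passed at neither.

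**Figure D4:**
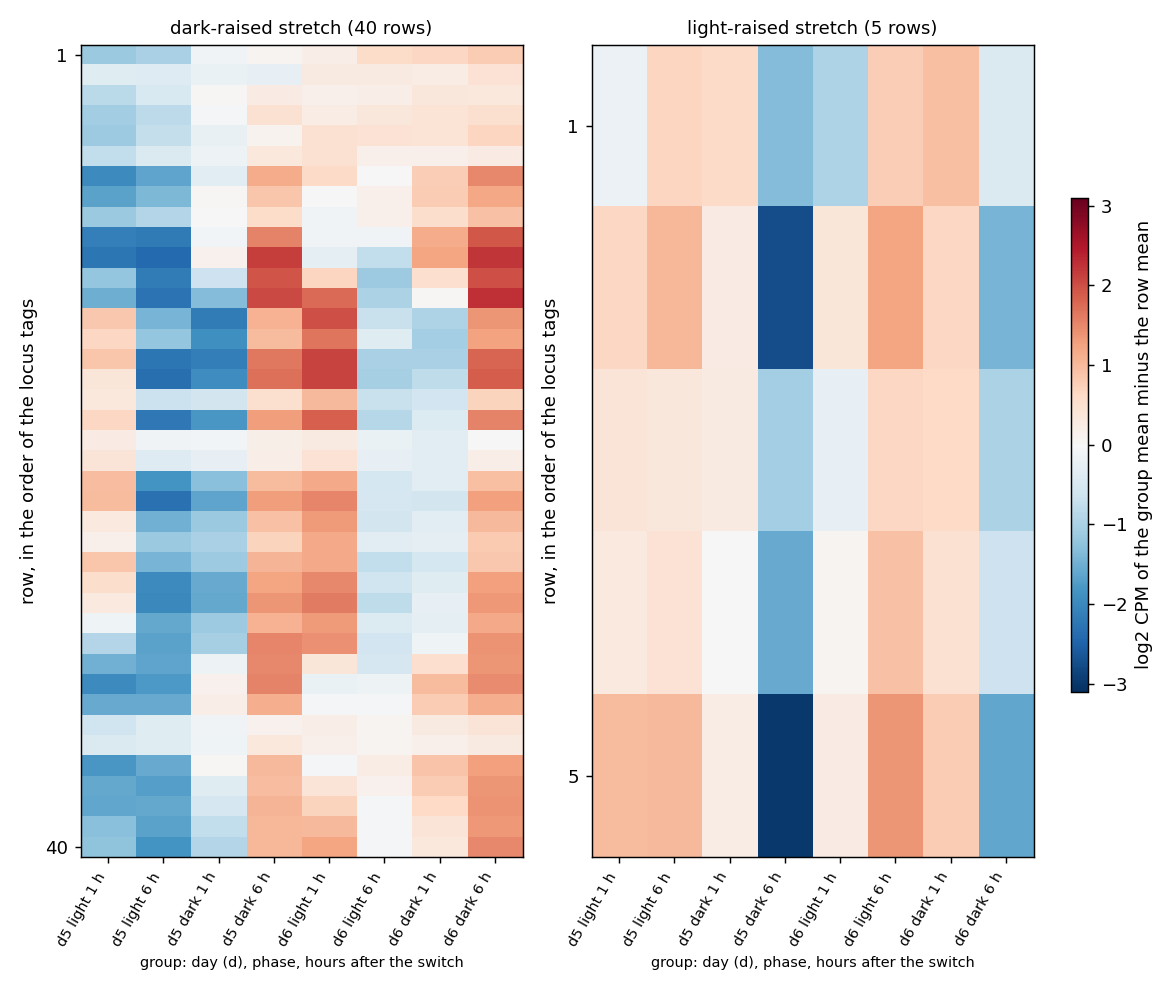
Rows are the 40 genes of the dark-raised stretch (left) and the 5 genes of the light-raised stretch (right) in the order of their locus tags, columns the 8 groups of days 5 and 6, and colour the log2 CPM of the group minus the mean of the gene. Genes in the middle of the dark-raised stretch are low at 6 h of light and 1 h of dark, and genes towards its ends are low at both light points of day 5.

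In the first hour after the switch to dark, with 6 h of light as the reference, 47 genes were called, 22 higher and 25 lower, of which 11 of the 22 were in the dark-raised stretch. E2E30_RS16265 rose 4.96-fold (log2 2.31 ± 0.28, adjusted p = 0.000310) and E2E30_RS16260 3.31-fold (1.73 ± 0.25, adjusted p = 0.000732). E2E30_RS14135 fell 1.64-fold (log2 -0.71 ± 0.10, adjusted p = 0.000685) and E2E30_RS11600 fell by 0.59 ± 0.09 on the log2 scale (adjusted p = 0.00198). The dark samples were the later ones here too, and the difference of these 2 genes between dark and light at 1 h went from -1.20 to -0.03 (adjusted p = 0.935) and from -0.68 to -0.18 (adjusted p = 0.417) with the drift-cancelling contrast. The block called 138 genes. With the days summed per culture, on day 6 alone, without culture B and without culture C, edgeR called 0 genes (232, 139, 180 and 457 at an unadjusted p below 0.05), so the calls of all 4 named genes were lost. For E2E30_RS16265 the log2 fold change was then 1.82, 2.08, 2.29 and 2.22, with adjusted p = 0.126, 1.00, 0.341 and 0.0933. For E2E30_RS16260 it was 1.11, 1.33, 1.63 and 1.71 (adjusted p = 0.778, 1.00, 0.481 and 0.0979), and on day 6 alone it was -0.40 for E2E30_RS14135 and -0.23 for E2E30_RS11600 (both adjusted p = 1.00). Without any of 7 single libraries (B or C of light 6 h and A or B of dark 1 h on day 5, A or C of light 6 h and B of dark 1 h on day 6) the count was 18 to 27.

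In the switch to light, with 6 h of dark as the reference, 4 of the 5 genes of the light-raised stretch were higher and 22 of the 40 genes of the dark-raised stretch lower, and the others did not pass the threshold. E2E30_RS05030 was 7.21-fold higher at 1 h of light (log2 2.85 ± 0.22, adjusted p = 1.68e-08) and E2E30_RS05015 5.83-fold (2.54 ± 0.27, adjusted p = 1.600e-06), while E2E30_RS16265 and E2E30_RS16260 were lower, with log2 fold changes of -3.51 ± 0.29 and -2.89 ± 0.26 (both adjusted p = 9.97e-08). Of all genes 954 were called, 504 higher and 450 lower (433 with the days summed per culture, 232 without culture B and 600 without culture C). On day 6 alone 13 were called, and E2E30_RS05015 and E2E30_RS16260 did not pass (log2 fold changes of 1.69 and -2.11, adjusted p = 0.128 and 0.0658). This comparison sets light samples against dark samples taken later on the same day. The single consecutive step, from 6 h of dark on day 5 to 1 h of light on day 6, called 177 genes, 141 higher and 36 lower, among them 4 higher in the light-raised stretch. In the dark-raised stretch 5 genes were lower, 1 was higher and 34 did not pass over this step, with a median log2 change of 0.11 against -0.59 in the comparison within days. Over the step E2E30_RS16265 went from 916 ± 247 to 165 ± 24.1 CPM and E2E30_RS16260 from 1349 ± 283 to 432 ± 104 CPM. E2E30_RS05030 went from 49.95 ± 12.5 to 471 ± 41.1 CPM and E2E30_RS05015 from 39.47 ± 6.98 to 349 ± 68.1 CPM.

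Between days the change was broad. Day 6 differed from day 5 in 2402 of 4063 genes, 1204 higher and 1198 lower, 135 of them by at least 2-fold. E2E30_RS06575 rose 3.98-fold (log2 1.99 ± 0.11, adjusted p = 9.64e-13) and E2E30_RS13390 3.21-fold (1.68 ± 0.15, adjusted p = 1.76e-09). E2E30_RS14135 fell by 2.20 ± 0.07 (adjusted p = 1.40e-16), step by step from 1386 ± 90.6 CPM at 1 h of light on day 5 to 349 ± 28.0 CPM at 6 h of dark, and from 201 ± 16.1 to 113 ± 18.3 CPM on day 6. E2E30_RS12255 fell by 1.91 ± 0.22 (adjusted p = 2.68e-07). In the dark-raised stretch 36 of 40 genes were higher on day 6, with a median of 1.92-fold.

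The dark minus light difference itself differed between the days for 314 genes, 139 with a larger value on day 6 and 175 with a smaller one. E2E30_RS04105 and E2E30_RS01835 had larger values by 1.32 ± 0.16 and 1.30 ± 0.16 (both adjusted p = 2.06e-05). E2E30_RS04105 lay at 265 ± 65.8 CPM at 1 h of light and 95.60 ± 8.08 CPM at 1 h of dark on day 5, and at 76.64 ± 13.97 and 84.91 ± 9.98 CPM on day 6. E2E30_RS09540 and E2E30_RS06575 had smaller values by -2.10 ± 0.38 and -1.58 ± 0.21 (adjusted p = 0.00175 and 6.28e-05). With the culture as a block 614 genes were called, and without culture B or C 17 or 103, with E2E30_RS09540 no longer called without culture B (adjusted p = 0.124). Fitted alone, day 5 called 1225 genes between dark and light over both hours and day 6 called 15.

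In the unreplicated day 4 pools, 39 of the 40 genes of the dark-raised stretch were higher at 6 h of dark than at 6 h of light, with a median log2 ratio of 3.09, and all 5 genes of the light-raised stretch were lower, with a median of -2.06. At 1 h 37 of the 40 genes of the dark-raised stretch were higher in the dark, with a median of 1.73, unlike the 13 called higher and 16 called lower on days 5 and 6. At 6 h of light and of dark E2E30_RS16265 lay at 50.68 and 902 CPM, and E2E30_RS05030 at 555 and 31.21 CPM. Of the 475 genes called at 6 h on days 5 and 6, 62.7% had the same direction on day 4 (95% exact Clopper-Pearson interval 58.2 to 67.1%), against 53.9% of all tested genes. The share was 51.8% for the 966 genes over both hours (48.6 to 55.0%, all genes 50.8%), 37.9% for the 480 genes at 1 h (33.6 to 42.4%, all genes 46.8%) and 70.2% for the 47 genes of the switch to dark (55.1 to 82.7%, all genes 49.9%). These intervals cover counting error only and treat genes as independent, which neighbouring genes are not.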

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

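The tests of gradual change on the genes outside the stretches and on the stretches themselves, the tests of abundant genes outside the stretches and of a shift common to all genes, the exchange of hours within cultures, the test of the change from day 5 dark to day 6 light and the grouping of the interaction splits by their weights were chosen after the results were seen. The others in this part were written down before their results were seen. The difference between dark and light depended on the hour for 46 genes and on the day for 314, by edgeR's interaction tests. The interaction with the hour was 6.47 ± 0.53 on the log2 scale for E2E30_RS16290 and 6.17 ± 0.49 for E2E30_RS16295, and -3.39 ± 0.30 for E2E30_RS05030 and -3.18 ± 0.37 for E2E30_RS05015. The interaction with the day was 1.32 ± 0.16 for E2E30_RS04105, 1.30 ± 0.16 for E2E30_RS01835, -2.10 ± 0.38 for E2E30_RS09540 and -1.58 ± 0.21 for E2E30_RS06575. The rule that named these 8 genes requires the same sign in all 3 cultures.

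The first pattern is the pair of stretches that differ between dark and light at 6 h. A gradual change over the sampling days that is linear or quadratic would leave little of it under the drift-cancelling contrast. The median log2 difference there was 1.62 for the dark-raised stretch (1.54 to 1.77 without each culture in turn, 2.07 with the fixed contrast). For the light-raised one it was -2.15 (-2.21 to -2.03, -1.80 fixed). These values argue against such a change as the source. The culture with the smallest median still had 1.54 and -1.68, so the difference was not carried by a single culture. The stretches were chosen from calls over these same libraries, which favours such an outcome. Relative to the median of the genes outside the stretches the values were 1.53 and -1.67. TMM scaling had already removed a shift common to all genes, so this decides nothing about one. Removal of the 10 most abundant genes left 2.07 and -1.80 but hardly moved the scaling, so it decides nothing. A response to the light phase remains a candidate explanation and so does the hour of the day, because each phase was always sampled at the same hours and no test here parts them. Reads shared between near-identical copies stay open as well, since no sequence was used.

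The second pattern is the large number of dark against light calls outside the stretches. Across the 940 such genes called over both hours, the slope of the drift-cancelling on the fixed log2 fold change was 0.13 (0.13 to 0.16 without each culture in turn), where a constant effect of phase gives 1 and a linear or quadratic drift 0, so a gradual change over the sampling days may account for most of these calls. The slope was higher, 0.329 and 0.296, across the 449 and 434 genes called at 1 h and at 6 h, and at 1 h the drift-cancelling contrast called 32 higher and 74 lower genes outside the stretches, against 1 and 1 at 6 h. These calls at 1 h do not tell a phase effect from a drift of another form, which the weights do not cancel. Among them, E2E30_RS06575 lay at 16.46 and 31.37 CPM at 1 h of light and of dark on day 5, and at 126 and 125 CPM on day 6. Its log2 difference at 1 h was 0.48 with the fixed contrast and -0.76 (adjusted p = 0.00987) with the drift-cancelling one. Removal of the 10 most abundant genes left 963 calls in all and the split of the libraries by an abundance ratio as a covariate left 971, against 966, but neither decides, because the removal moved the median of all genes by only 0.01 on the log2 scale and no gene was called between the sets in edgeR (519 at an unadjusted p below 0.05). A phase effect that shrinks with culture time on top of a drift stays open, because it is not parted from a drift that slows.

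The third pattern is that day 6 alone gave 15 calls between dark and light and day 5 alone 1225. The median depth of day 6 libraries was 0.821 of that of day 5 (7563298 against 9209463 counts). The common biological coefficient of variation was 1.05 times that of day 5 (14.6 against 13.9%). This argues against depth and against a larger spread over all genes as the cause. In the dark-raised stretch the SD of the mean log2 CPM was larger on day 6 at each point, with 0.58 against 0.18 at 1 h of dark and 0.60 against 0.41 at 6 h of dark. In the light-raised stretch it was larger on day 6 at both dark points and smaller at both light points. A larger spread on day 6 stays open for genes of the stretches. Across the 1194 genes called on day 5 outside the stretches, the slope of the change from day 5 dark to day 6 light on the day 5 log2 fold change was 0.4996 (0.478 to 0.498 without each culture in turn). A shrinking phase effect with no other change over time gives no positive slope, and -1 where the light level stays fixed. Error in the day 5 dark values gives -1. The positive slope argues against both as the whole cause. The slope of the day 6 on the day 5 log2 fold change, 0.157 (0.138 to 0.168), decides nothing, because choosing genes by their day 5 difference lowers it, so a gradual change that slows stays open, with or without a phase effect that shrinks. In the stretches the median differences at 6 h were 2.67 and 1.55 on days 5 and 6 for the dark-raised and -2.07 and -1.64 for the light-raised stretch.

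Other splits of the same libraries were run, 100 per comparison, the real one included. Labels were exchanged within days and hours or within the 2 groups compared, and in a second set only within cultures. Only 32 splits within cultures exist for the comparisons at 1 h, at 6 h, of the switches and within a phase, so 1 in 32 is the smallest share there. No correction was made over the 10 comparisons. The splits make chance less likely as the source of the counts but do not exclude it. For the interaction with the hour they were not enough, and a further test was run. As many genes as the real split were reached by 1 split for dark against light over both hours (966 genes, at most 69 in another split), at 1 h (480, at most 309) and at 6 h (475, at most 316), for the switch to light (954, at most 791), for 6 h against 1 h in light (34, at most 29) and for the days (2402, at most 2). For the interaction with the hour 3 splits did so (46, at most 153), for the switch to dark 3 (47, at most 54), for 6 h against 1 h in dark 2 (76, at most 120) and for the interaction with the day 2 (314, at most 437). When labels were exchanged only within cultures, which parts as many pairs as the real split, no other split reached the real count in the 8 comparisons that are not interactions, with at most 524 over both hours, 240 at 1 h, 236 at 6 h, 41 and 694 for the switches to dark and to light, 2 and 33 within light and dark, and 1876 between days. Of these splits 6 of 100 reached the count of the interaction with the hour (at most 725) and 4 of 100 that of the interaction with the day (at most 711). A split that exchanges the phase labels in all cultures at 1 hour or on 1 day weights all 12 culture pairs as the plain difference between dark and light. The 5 other splits that reached 46 genes did so for 10, 11, 8, 11 and 7 of the 12 pairs (725, 711, 486, 206 and 60 genes). Any split has at least 6 such pairs by construction, and other splits with 7, 8 or 9 of them called 0 genes. The weights therefore do not tell which splits reach the count. Exchanging the hours of light and dark together within a culture and day keeps the plain difference between dark and light in place. Of the 32 such exchanges, all that exist, only the real order reached 46 genes (at most 15 in another). With limma on the difference per culture and day the real order gave 30 genes and no other gave any. This makes chance less likely for this count but does not exclude it. A share of 1 in 32 is the smallest this test can give, and the test was chosen after the results were seen.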

How the results depend on the processing

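The drift-cancelling contrast, the consecutive step into light and the split of the libraries by an abundance ratio were added after the data were seen; all other alternatives were fixed before the data were examined. The counts of called genes that moved by more than 1.5 times were as follows, and the first 3 settings use fewer libraries or an added fold by their construction. With days summed per culture they were 246 (both hours), 140 (1 h), 57 (6 h), 0 (switch to dark, 232 at an unadjusted p below 0.05 in edgeR), 433 (switch to light), 21 (within light) and 47 (within dark). On day 6 alone they were 15, 15, 11, 0 (139 unadjusted), 13, 0 (174 unadjusted) and 2 in the same order, and day 5 alone moved only the switch to dark, to 80. With a fold of at least 2 they were 20, 29, 41, 10, 40, 19 and 33 in that order, 29 for the interaction with the hour, 135 between days and 48 for the interaction with the day. The culture as a replicate block, which adds the pairing, gave 721 (1 h), 775 (6 h), 138 (switch to dark), 76 (within light), 160 (within dark), 90 (interaction with the hour) and 614 (interaction with the day), and moved no other count by more than 1.5 times. DESeq2 gave 110 for the switch to dark, 60 within light, 120 within dark and 83 for the interaction with the hour. The drift-cancelling contrast gave 58, 124 and 36 for both hours, 1 h and 6 h, and the consecutive step into light, which sets 3 against 3 libraries and reverses their order in time, gave 177. For the block, DESeq2, this contrast and this step the cause was not tested. RLE scaling, no filter, a mean count of at least 50, removal of the 10 most abundant genes and the abundance-ratio split moved no count by more than 1.5 times, and RLE and the removal shifted no share of higher calls by more than 10 points.

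Leaving out 1 culture or 1 library gave 234 to 1019 genes over both hours, 75 to 525 at 1 h, 46 to 563 at 6 h, 23 to 58 for the interaction with the hour, 0 to 69 for the switch to dark, 232 to 973 for the switch to light, 0 to 48 within light, 11 to 107 within dark, 1748 to 2387 between days and 17 to 454 for the interaction with the day. Each of these lowest counts came without culture B. For the switch to dark, edgeR called 0 genes without culture B (180 unadjusted) and 0 without culture C (457 unadjusted), and within light 0 without culture B (149 unadjusted). Single libraries moved 3 counts. For 6 h it was 303 without day 5 light 6 h B, 308 without day 5 light 6 h C and 295 without day 6 dark 6 h B. For the switch to dark it was 21 without day 5 light 6 h B, 20 without day 5 light 6 h C, 21 without day 5 dark 1 h A, 18 without day 5 dark 1 h B, 27 without day 6 light 6 h A, 27 without day 6 light 6 h C and 19 without day 6 dark 1 h B. Within light it was 21 without day 5 light 1 h C, day 5 light 6 h A or day 6 light 6 h A, and 22 without day 6 light 1 h B. The 40 log2 fold changes of 18 named genes kept their sign in all 552 alternatives run and their side of the threshold in 509. The rule for named genes favours this, because it takes the largest changes with the same direction in all 3 cultures. The added fold reuses the same fit and so keeps every sign. The drift-cancelling contrast was run only for the comparisons of dark with light. The day 4 shares among genes of above-median abundance were 54.4% (both hours), 39.6% (1 h), 65.0% (6 h) and 76.3% (switch to dark), each inside the interval of the main share. The alternatives for gene lists were not run, since no list could be matched, and counting error weighs most in the shallowest libraries, which are day 6 dark 1 h C with 1570862 counts and the 4 pools of day 4 with 1670201 to 2696986.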

Other observations

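The test of the class of 14 genes was chosen after its values were seen, as were the splits by neighbours and by abundance. Calls clustered along the table in every comparison. At 6 h, 128 neighbouring pairs of genes were called in the same direction between dark and light, against a mean of 27.6 and a maximum of 48 in 10000 permutations of the calls over the rows (one-sided permutation p = 0.0001, the smallest they can give). For the interaction with the hour there were 25 such pairs against at most 5. The other 8 comparisons also lay above their permuted maximum, from 12 pairs against at most 4 for the switch to dark to 1163 against at most 788 between days. Neighbouring genes that share a transcript would give such clustering. Beyond the 2 stretches weighed above, 8 runs of at least 5 calls at 6 h had medians over their genes between -0.48 and 0.54 on the log2 scale.

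The 14 genes of the dark-raised stretch that were lower in the dark at 1 h and higher at 6 h had their low points at 6 h of light and 1 h of dark. From 6 h of dark on day 5 to 1 h of light on day 6 all 14 had higher values, with a median log2 change of 0.45 (0.30 to 0.48 without each culture in turn) and none called. Over the following 5 h of light their median fell by 2.09. A hypothesis is that levels kept from the preceding dark phase into the first hour of light make these genes look lower in the dark at 1 h, but the value of 0.45 does not test it, because the genes were chosen for high values at 1 h of light and 6 h of dark. In the day 4 pools 13 of the 14 were higher in the dark at 1 h, with a median log2 ratio of 0.93, and their median changed by 0.75 from 1 h to 6 h of light. The 13 genes of the stretch that were higher in the dark at both hours had a median change of -0.69 over the same step into light on day 6.

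A few locus tags took most of the counts. E2E30_RS00735 took 23.9% of all counts and 7.59 to 37.1% of a library, and E2E30_RS04265, E2E30_RS17170 and E2E30_RS14350, chosen after their values were seen, took 11.1, 10.3 and 9.55%. The ratio of E2E30_RS17170 to E2E30_RS04265 divided the 24 libraries into 12 between 0.852 and 0.907 and 12 between 0.962 and 0.999, and the 4 pools of day 4 lay between 0.834 and 0.873. All 3 libraries of 1 h of light on day 6 were in the lower set. Of culture B only the library of 1 h of dark on day 6 was in the upper set, while most libraries of cultures A and C were. The split is thus partly confounded with culture. No gene differed between these sets of libraries beyond the groups in edgeR at an adjusted p below 0.05, 519 did at an unadjusted one, and no source for the split was tested.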
